A study of Homo sapiens with 16 samples.

How the data were processed

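Vastus lateralis biopsies of 4 lean and 4 obese adults, taken before and after a single bout of exercise, gave 16 libraries of polyadenylated RNA, 1 per person and time. Per the submitters' processing notes, reads were processed with STAR, featureCounts and edgeR against hg38. Their versions, the alignment settings, the strand setting and the annotation release were not given in the sources used here. The deposited table holds 64253 genes with Ensembl identifiers, symbols and hg38 coordinates, which are used as given. Its values are a normalized signal (not coverage along the genome), deposited by the authors as CPM scaled by a factor per library. The column sums divided by 1e6 ran from 0.845 to 1.12 with a geometric mean of 1, where plain CPM would give 1 in each, while the design had assumed plain CPM. Every value was a whole multiple of the smallest value of its column, so whole reads could be recovered for 100% of values (within 0.01 of a whole number). Gene reads totalled 27.6e6 to 47.3e6 per library. A level of 3 reads corresponded to 0.0581 to 0.106 CPM, and such floors cover counting error only, since reads without molecular identifiers are not independent molecules.

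Replicates are separate people, numbered as in the labels, and the same number before and after marks the same person according to the design text. After removal of group means the libraries of a person correlated at r = 0.365 to 0.796, and in 8 of 8 people the library before exercise correlated best with the person's own library after it. No pair of libraries agreed within sampling noise (smallest chi-square per degree of freedom 27.6), so none was merged. The labels gave no sequencing batch. Genes on the Y chromosome, XIST and related transcripts were left out of every test and every output.

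Genes with at least 1 CPM in at least 4 libraries were tested (14297 genes, 12490 of them protein coding, holding at least 99.6% of reads, 8 on alternate contigs). Values were analysed as log2(CPM + 0.5) with limma 3.58.1 in R 4.3.3, with a mean-variance trend, 2-sided moderated tests and Benjamini-Hochberg (BH) adjustment, and an adjusted p under 0.05 was the threshold. Fold changes on this scale understate the change of low genes. Changes with exercise and their difference between groups were estimated in 1 fit of all 16 libraries with a term per person (the replicate block). Obese and lean people were compared before and after exercise in separate fits of 8 libraries. Genes were named by a rule, namely the 12 largest changes in each direction among genes past the threshold with a mean of at least 5 CPM and, after exercise, the same direction in every person. Where fewer than 10 genes passed, the 5 with the smallest p in each direction were added and described as not past the test, and up to 4 members with the smallest p were taken from each list. Design, thresholds, naming rule, gene lists and the alternatives listed below, unless said otherwise, were chosen before the data were examined.

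The 40 gene lists cover pathways of exercised muscle, fibre types and markers of other cell types that a needle biopsy can hold. Members were matched by symbol and then by older symbol, and 36 lists with at least 3 tested genes were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the lists of a comparison. Camera was repeated with an estimated correlation, which left 0 of the called lists in any of the 6 comparisons, and fry was run on the same lists. The share of members past the threshold is given over all genes tested and adjusted over the list alone. For each person the mean change or level over a list was also tested exactly, with 70 assignments of 4 of 8 people (smallest p = 0.0286) or 256 sign flips (smallest p = 0.00781). The overlap of calls was tested with Fisher's exact test, which treats genes as independent, so its p is descriptive. Correlations across genes are given without a p, since genes are not independent replicates.

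Alternatives included other pseudocounts (0.1 and 2), no filter, a mean of at least 5 CPM, rescaling to equal medians, quantile normalization, no variance trend, robust variances, array weights, fits with no replicate block or with the person as a random block, and each person left out in turn. Recovered reads were tested with edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0. Thinning to equal depth and removal of trends with GC content or length (lowess, span 0.3) were added after seeing the data. GC content was that of the longest reference transcript of a gene and was known for 98.8% of tested genes. Values were read with the R package data.table (1.17.8), and figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

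The fits were tested on simulated counts drawn from the real means and library sizes, with 200 of 14297 genes changed. Of genes changed 2-fold, 70.1% were recovered for lean exercise, 74.6% for obese exercise, 92.5% for the mean, 38.8% for the difference in response and 26.9% for each comparison of obese with lean muscle. For 4-fold changes these were 95.5%, 97.0%, 100%, 80.3%, 83.3% (before) and 78.8% (after), and for 1.5-fold changes 37.3%, 37.3%, 68.7%, 11.9%, 1.49% and 2.99%. False calls made up 2.63% to 7.45% of calls, and 0 recovered genes had the wrong sign. Each gene was drawn independently, with no trend shared across a library such as that with GC content in the real data. These rates therefore hold for that simpler setting and can differ in the real libraries.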

Results

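Gene expression was measured by sequencing of polyadenylated RNA in biopsies of the vastus lateralis, a muscle of the thigh, from 4 lean and 4 obese adults. Each person gave 1 biopsy before and 1 after a single bout of exercise, so the 16 libraries formed 4 groups of 4 (lean before, lean after, obese before and obese after). The type of exercise and the interval to the later biopsy were not given in the sources used here. No group was biopsied at both times without exercise. Changes after exercise, those of circadian clock genes included, were therefore not separated from time of day or a repeated biopsy. Reads assigned to genes numbered 31.4e6 to 39.9e6 per library in lean muscle before exercise and 38.0e6 to 46.7e6 after it. In obese muscle they numbered 27.6e6 to 47.3e6 before and 30.5e6 to 46.0e6 after. Levels are in counts per 1e6 gene reads as scaled in the deposited data (CPM), given as mean ± SD with n = 4 people per group. Changes are in log2(CPM + 0.5) ± SE from limma. At this depth 3 reads correspond to 0.0581 to 0.106 CPM, a floor that covers counting error only. Transcripts encoded by mitochondrial DNA took 13.3% ± 4.10 (SD, n = 4) of reads in lean muscle before exercise and 11.7% ± 4.29 after, and 11.7% ± 1.63 and 11.3% ± 2.93 in obese muscle.

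The first comparison asked which transcripts changed with exercise in lean muscle. Genes with the largest increases were named by the rule set in advance. NR4A3, an orphan nuclear receptor induced early after stimulation (chromosome 9, 99821855 to 99866891, hg38, protein coding), went from 1.03 ± 0.777 to 1026 ± 600 CPM, a log2 change of 9.30 ± 0.89 (limma, BH-adjusted p = 0.000105). Its relative NR4A1 (chromosome 12, 52022832 to 52059507) rose from 14.6 ± 3.07 to 403 ± 290 CPM, by 4.44 ± 0.53. PPARGC1A, a transcriptional coactivator of mitochondrial biogenesis (chromosome 4, 23755041 to 23904089), rose from 48.3 ± 12.9 to 765 ± 276 CPM, by 3.93 ± 0.42 (adjusted p = 0.000263). MAFF, a small MAF transcription factor, rose by 5.07 ± 0.72, ANKRD1, a stress-responsive ankyrin repeat protein of striated muscle, by 3.84 ± 0.80, EGR1, a zinc-finger transcription factor, by 3.32 ± 0.81 and ABRA, an actin-binding protein of striated muscle, by 3.07 ± 0.29. PRKAG2, a regulatory subunit of AMP-activated protein kinase, rose by 2.87 ± 0.37. FNIP2, a folliculin-interacting protein, rose by 2.92 ± 0.27 and SLC25A25, a mitochondrial carrier, by 2.79 ± 0.51. SYNJ2, a phosphoinositide phosphatase, rose by 2.59 ± 0.31.

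By the same rule 12 genes were named among those that fell in lean muscle. ARRDC2, an arrestin domain protein (chromosome 19, 18001132 to 18014102) went from 126 ± 15.9 to 22 ± 8.0 CPM, a log2 change of -2.55 ± 0.20 (limma, adjusted p = 4.04e-05). TXNIP, an inhibitor of thioredoxin and of glucose uptake (chromosome 1, 145992435 to 145996600), went from 1830 ± 343 to 529 ± 164 CPM, a change of -1.82 ± 0.24. DDIT4, an inhibitor of mTORC1, changed by -2.05 ± 0.29, GADD45G, a stress sensor, by -1.67 ± 0.22 and PFKFB3, a regulator of glycolysis, by -1.56 ± 0.26. The other 7 genes named in this direction, TSPAN8, PLEKHH3, CDKN2B, AVIL, ENAM, NNMT and UNKL, changed by -1.15 to -0.96. In all, 480 genes rose and 133 fell of 14297 tested, and 2317 had an unadjusted p under 0.05 where 714.85 were expected by chance. The change was at least 2-fold for 176 of the 613, and 607 moved the same way in all 4 people. The count was 256 to 362 when any 1 of the 4 lean people was left out (362, 256, 317 and 355 without persons 1 to 4), 99 without the filter on low values, 375 without a variance trend and 72 with no replicate block.

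**Figure D1:**
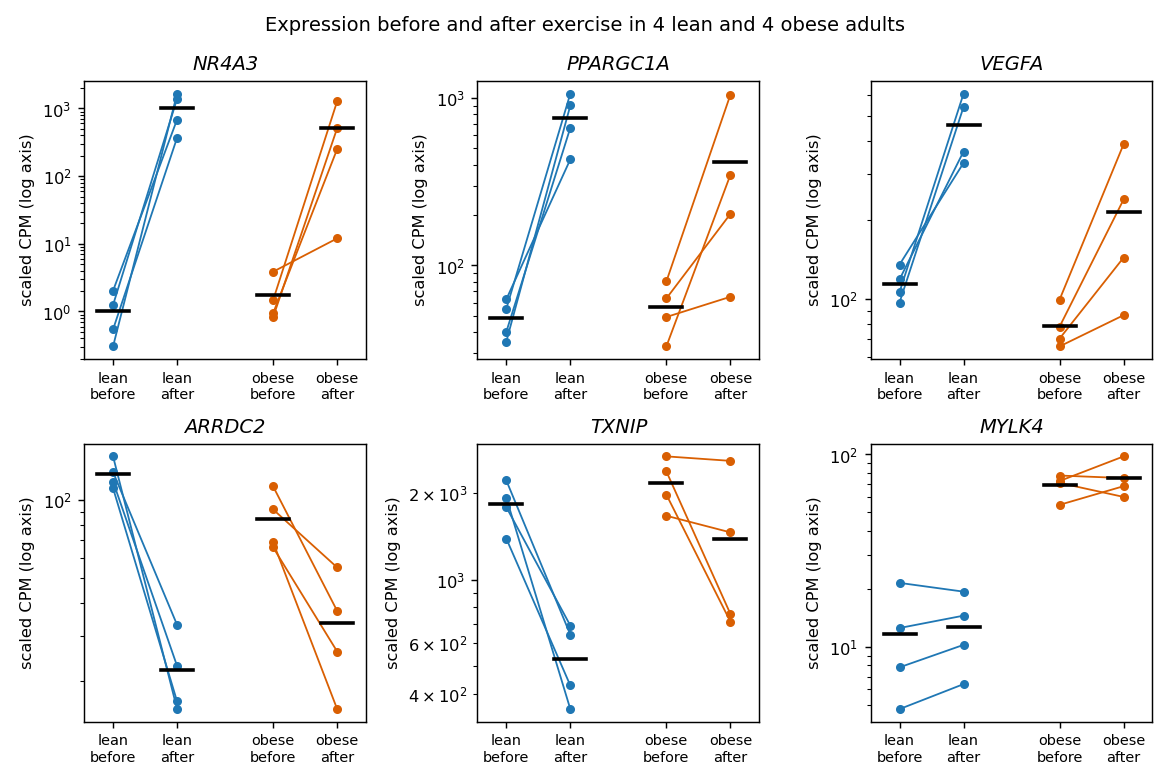
Expression of 6 genes in each person before and after exercise, with scaled CPM on a log axis, 1 point per library, a line joining the 2 libraries of a person (blue lean, orange obese) and a black bar at each group mean. NR4A3, PPARGC1A and VEGFA were higher and ARRDC2 and TXNIP lower after exercise in 8 of 8 people, while MYLK4 was at 11.6 CPM on average in lean and 69.1 CPM in obese muscle before exercise.

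Fixed gene lists described the response of lean muscle by function. Of 28 tested regulators of oxidative metabolism and fuel use, 7 rose and 1 fell (9 and 1 adjusted over the list alone). Besides PPARGC1A these included HK2, which encodes the hexokinase of working muscle, at 2.19 ± 0.27, IRS2, an insulin receptor substrate, at 1.41 ± 0.23, and PERM1, a regulator of PPARGC1 action in muscle, at 1.21 ± 0.17. The member that fell was TXNIP. Limma's camera test called this list (adjusted p = 0.00259, and adjusted p = 0.349 with an estimated correlation). Of 22 angiogenesis and hypoxia targets 3 rose and 1 fell (9 and 2 adjusted over the list alone; camera adjusted p = 0.00284, adjusted p = 0.349 with an estimated correlation). VEGFA, the main vascular growth factor (chromosome 6, 43770184 to 43786487), went from 114 ± 16.5 to 460 ± 134 CPM, and its receptor KDR rose by 1.13 ± 0.19 and the angiopoietin receptor TEK by 1.01 ± 0.15. Of 19 circadian clock genes 4 rose and 0 fell (5 and 0 adjusted over the list alone), with BHLHE40 at 2.16 ± 0.41, NFIL3 at 1.16 ± 0.28 and BHLHE41 at 0.73 ± 0.15. Camera gave an adjusted p = 0.000159 for the clock list, and adjusted p = 0.349 with an estimated correlation. Heat shock proteins and co-chaperones had 3 of 24 members that rose and 1 that fell (6 and 1 adjusted over the list alone; camera adjusted p = 0.000159, adjusted p = 0.818 with an estimated correlation). DNAJB4 and DNAJB5 each rose by 0.97 ± 0.17 and HSP90AA1 by 0.55 ± 0.14, while DNAJB1 changed by -0.49 ± 0.10.

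Immediate early genes and muscle atrophy genes held many changed members in lean muscle without a call by camera. Of 30 immediate early genes 7 rose and 2 fell (11 and 6 adjusted over the list alone; camera adjusted p = 0.103). Of 19 atrophy genes and ubiquitin ligases 5 rose and 0 fell (6 and 3 adjusted over the list alone; camera adjusted p = 0.0685). The muscle ubiquitin ligase TRIM63 went from 291 ± 60 to 1633 ± 747 CPM and FBXO32 from 642 ± 203 to 1476 ± 593 CPM. Glucocorticoid-responsive genes had 3 that rose and 2 that fell of 19 (4 and 3 adjusted over the list alone), with CEBPD at -1.75 ± 0.21 and TSC22D3 at -0.81 ± 0.12. Myogenic regulators had 3 that rose and 2 that fell of 24 (4 and 4 adjusted over the list alone). Of these MYOG, a myogenic transcription factor, changed by -0.88 ± 0.16 and PAX3, a factor of muscle progenitors, by -1.51 ± 0.29.

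Several lists lay lower after exercise in lean muscle with small changes per gene. Of 24 interferon-stimulated genes 20 were lower, with a median of -0.30, and 2 fell (0 rose and 6 fell adjusted over the list alone), MX1 at -0.58 ± 0.15 and IFI44L at -0.79 ± 0.20, both products of antiviral genes. Camera gave an adjusted p = 2.92e-05 for this list, and adjusted p = 0.349 with an estimated correlation. Of 56 nuclear-encoded subunits of oxidative phosphorylation 55 were lower, with a median of -0.14, but 0 passed per gene over all genes or adjusted over the list alone (camera adjusted p = 2.92e-05, adjusted p = 0.877 with an estimated correlation). The 13 mitochondrially encoded mRNAs were all lower, with a median of -0.27 and 0 past the test on either scale (camera adjusted p = 0.00143, adjusted p = 0.877 with an estimated correlation). Of 16 fast fibre genes 13 were lower, median -0.22, with 0 past the test on either scale (camera adjusted p = 0.00359, adjusted p = 0.818 with an estimated correlation). Among markers of other cell types, 2 of 7 Schwann cell and nerve markers rose (3 and 0 adjusted over the list alone), PMP22, a myelin protein, by 2.19 ± 0.33 and MBP, myelin basic protein, by 0.54 ± 0.11 (camera adjusted p = 0.0338, adjusted p = 0.713 with an estimated correlation). Over these 7 nerve markers the median was 0.12 and the mean 0.52, with 5 higher and 2 lower. Of 19 endothelial markers 3 rose and 1 fell, the same numbers as adjusted over the list alone. PECAM1 rose by 0.66 ± 0.17 and CLDN5, a junction protein of endothelium, changed by -0.95 ± 0.23. Of the 36 lists tested, camera called 9 in lean muscle, and 4 of the 8 swaps of before and after within people, the real order included, gave as many.

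In obese muscle, the same comparison gave 14 genes that rose and 3 that fell of 14297 tested, with 1273 at an unadjusted p under 0.05. NR4A3 again showed the largest increase, from 1.78 ± 1.42 to 514 ± 550 CPM, a log2 change of 6.72 ± 0.89 (limma, adjusted p = 0.0217). VGLL2, a cofactor of TEAD transcription factors, went from 60.5 ± 22.3 to 246 ± 153 CPM and rose by 1.80 ± 0.28. SLC19A2, a thiamine transporter, went from 52.8 ± 10.2 to 147 ± 74.7 CPM and rose by 1.35 ± 0.20. PFKFB2, which controls the level of fructose bisphosphate in glycolysis, rose by 0.99 ± 0.13, from 28.3 ± 13.5 to 56.3 ± 27.9 CPM. The adaptor BCAR3 rose by 1.17 ± 0.20 and CPEB4, a regulator of mRNA polyadenylation, by 0.87 ± 0.15. C20orf194, PDE7A, LINGO4, DDIT4L, ANKRD9 and the long noncoding RNA CASC7 also rose, by 0.69 to 1.26. ARRDC2 changed by -1.44 ± 0.20 (adjusted p = 0.0255), GADD45G by -1.30 ± 0.22 and TOB2, an antiproliferative factor, by -0.60 ± 0.10. PPARGC1A was at 56.5 ± 20.2 CPM before and 415 ± 436 CPM after, a difference of 2.29 ± 0.42 that did not pass (adjusted p = 0.0573). The change was at least 2-fold for 9 of the 17, and all 17 moved the same way in all 4 people.

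Per list, 1 immediate early gene rose and 1 fell in obese muscle (2 and 1 adjusted over the list alone), and 0 members of the metabolic, clock, angiogenesis and atrophy lists passed over all genes. Adjusted over the list alone, 7 of 19 clock genes, 6 of 28 metabolic regulators, 5 of 22 angiogenesis targets and 3 of 19 atrophy genes rose, and 1, 1 and 0 of the last 3 lists fell. The median log2 difference was 0.28 over the clock genes (camera adjusted p = 7.99e-05, adjusted p = 0.450 with an estimated correlation). It was -0.20 over the 24 interferon-stimulated genes, of which 20 were lower (0 fell over all genes and 1 adjusted over the list alone; camera adjusted p = 7.99e-05, adjusted p = 0.450 with an estimated correlation). Metabolic regulators (camera adjusted p = 0.0425), atrophy genes (0.0234) and insulin signalling genes (0.0443) were also called as higher, each with adjusted p = 0.450 with an estimated correlation. Camera also called lists of transcripts of other cell types. Red blood cell transcripts had a median difference of 1.2, with 4 of 5 passing adjusted over the list alone and 0 over all genes (camera adjusted p = 0.000522, adjusted p = 0.450 with an estimated correlation). HBB, the beta chain of haemoglobin, was at 185 ± 58.7 CPM before and 472 ± 176 CPM after. HBA1 and HBA2 are near-identical copies, so their separate values are uncertain. Adipocyte markers had a median of -0.43 over 13 genes (camera adjusted p = 0.00158, adjusted p = 0.450 with an estimated correlation) and smooth muscle and pericyte markers -0.22 over 15 (camera adjusted p = 0.0260, adjusted p = 0.725 with an estimated correlation), with 0 genes past the test on either scale. Of the 8 swaps of before and after within people, 6 gave at least as many camera calls as the 8 found.

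The count of 17 in obese muscle rested on a few people and on the settings. It was 0 without person 7 or lean person 2, 1 without person 6, 5 without person 1, 11 without person 3 and 87 without person 5. The genes called changed as well. Without person 8, 20 genes were called but only 8 of the 17 were among them, while 15 of the 17 stayed called without person 5. It was 0 when the obese group was fitted alone with its replicate block, 0 with no filter, 1 with no replicate block, 36 with rescaling to equal medians, 13 with edgeR and 162 with DESeq2. The share of higher calls, 82.4%, was 72.2% with quantile normalization and 71.4% with robust variances, and 94.1% with the GC trend removed, a setting chosen after seeing the data.

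Averaged over both body-weight groups, 606 genes rose and 234 fell (2652 at an unadjusted p under 0.05). NR4A3 rose by 8.01 ± 0.63, PPARGC1A by 3.11 ± 0.29, VGLL2 by 2.17 ± 0.20, SLC19A2 by 1.75 ± 0.14 and VEGFA by 1.61 ± 0.16, each in 8 of 8 people (limma, adjusted p from 1.84e-05 to 0.00013). ARRDC2 changed by -1.99 ± 0.14, MYOG by -0.85 ± 0.11 and TFEB, a regulator of lysosomal genes, by -0.75 ± 0.13, in the same 8 of 8. MT1E, a metallothionein with close paralogs that can share its reads, changed by -1.05 ± 0.24. Of 24 interferon-stimulated genes 21 were lower and 6 fell (0 rose and 7 fell adjusted over the list alone), among them OAS2 at -0.54 ± 0.12, OAS3 at -0.62 ± 0.14, MX1 at -0.50 ± 0.10 and IFI44L at -0.68 ± 0.14. Camera gave an adjusted p = 4.16e-06 for this list, and adjusted p = 0.312 with an estimated correlation. Each person's mean over the list changed by -0.26 ± 0.12 (SD, n = 8), lower in 8 of 8 people, with an exact 2-sided sign-flip p = 0.00781, the smallest possible, and 0.0938 adjusted over 36 lists. Clock genes had 6 of 19 that rose and 0 that fell (12 and 0 adjusted over the list alone; camera adjusted p = 1.16e-05, adjusted p = 0.339 with an estimated correlation), with BHLHE40 at 1.78 ± 0.29. Metabolic regulators had 8 of 28 that rose and 1 that fell (9 and 2 adjusted over the list alone; camera adjusted p = 0.00612, adjusted p = 0.351 with an estimated correlation). Angiogenesis targets had 4 of 22 that rose and 1 that fell (8 and 2 adjusted over the list alone; camera adjusted p = 0.00612, adjusted p = 0.339 with an estimated correlation). These 4 lists also passed fry, which tests whether a list moves on balance one way without comparing it with other genes (adjusted p = 0.0247 for interferon and 0.0378 for the other 3). The count of 840 became 298 with no filter, 149 with no replicate block, 545 without person 6 and 542 without person 7.

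The central comparison asked whether the response to exercise differed between obese and lean muscle. With limma, 0 of 14297 genes differed in their response (smallest adjusted p = 0.995), 662 had an unadjusted p under 0.05 where 714.85 were expected, and edgeR and DESeq2 called 0 and 2 genes. The 2 from DESeq2 were C1orf158 and LRRC66, the first named after its value was seen. The groups' changes did not overlap for 2.64% of genes, where chance gives 2.86%. The genes with the smallest p included ABRA, whose obese minus lean difference was -1.74 ± 0.42, AKAP13, an anchoring protein of protein kinase A, at -0.88 ± 0.19, RBM12 at -0.64 ± 0.14, JMJD1C at -0.64 ± 0.15 and CPEB4 at -0.85 ± 0.21. In the other direction they were LRRC66 at 1.2 ± 0.24, YPEL1 at 0.93 ± 0.22, SLC22A3, a cation transporter, at 0.98 ± 0.23, HDAC4, a histone deacetylase active in muscle, at 0.67 ± 0.17 and ARRDC2 at 1.11 ± 0.28, and all 10 had an adjusted p = 0.995. PPARGC1A differed by -1.64 ± 0.59 with the same adjusted p. Leaving out lean person 4 gave 4 genes, the haemoglobin genes HBB, HBD, HBA1 and HBA2, also named after their values were seen.

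The lean and obese responses were alike in direction. Of the 14 genes that rose in obese muscle 13 also rose in lean muscle, against 0.470 expected from independent lists (Fisher's exact p = 7.98e-19), and all 3 that fell also fell in lean muscle, against 0.0279 expected (Fisher's exact p = 7.87e-07). Both lists come from 1 fit with a shared variance per gene, and Fisher's test treats genes as independent. The expected numbers and these p-values are therefore descriptive only. Across all tested genes, which are not independent replicates, the log2 changes of both groups correlated with Pearson's r = 0.608 and Spearman's rho = 0.426. Of the 613 genes called in lean muscle 96.4% had the same sign in obese muscle. Of the 840 genes called on average 85.8% had the larger change in lean muscle, with a median ratio of obese to lean change of 0.623. Taken per person over these genes, the mean change in the called direction was 0.82 ± 0.10 in lean (SD, n = 4) and 0.52 ± 0.25 in obese people (SD, n = 4), with an exact 2-sided permutation p = 0.0857. The 2 groups overlapped, at 0.70 to 0.91 and 0.27 to 0.80. The number of genes shared, 16, was 0 to 76 when 1 person was left out, with 0 without person 2 or person 7, 1 without person 6, 5 without person 1, 10 without person 3 or person 4 and 76 without person 5.

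**Figure D2:**
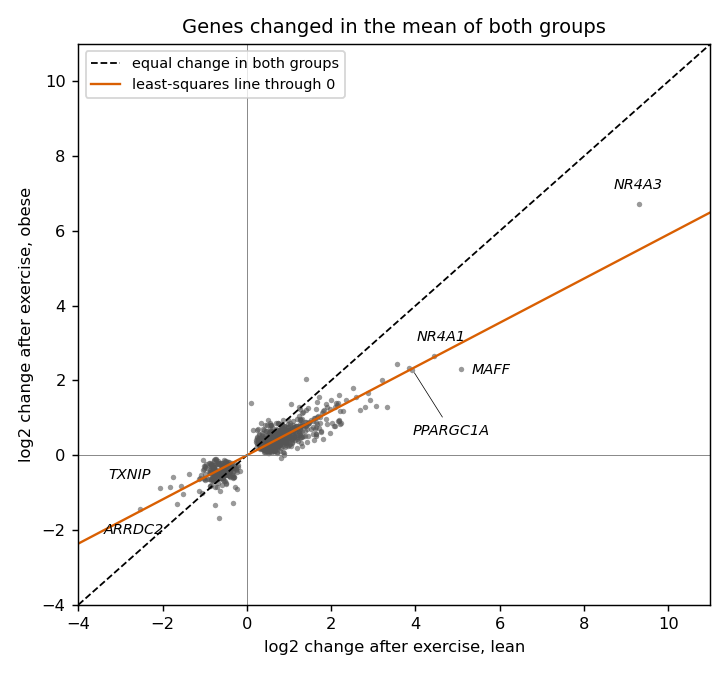
Log2 change after exercise in lean muscle (horizontal) against that in obese muscle (vertical) for the 840 genes called in the mean of both groups, 1 point per gene. The dashed line marks equal change and the orange line is a least-squares fit through 0 with a slope of 0.591; most points lie closer to 0 in obese than in lean muscle.

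Some lists differed in response by camera although 0 genes did. Nuclear-encoded subunits of oxidative phosphorylation had a median obese minus lean difference of 0.17, with 54 of 56 above 0 (camera adjusted p = 4.74e-08, adjusted p = 0.877 with an estimated correlation). Fast fibre genes had a median of 0.34 over 16 (camera adjusted p = 0.000131, adjusted p = 0.877 with an estimated correlation) and red blood cell transcripts 1.41 over 5 (camera adjusted p = 1.74e-05, adjusted p = 0.835 with an estimated correlation), with 4 of the 5 passing adjusted over the list alone. Heat shock genes had a median of -0.16 over 24 (camera adjusted p = 0.000996, adjusted p = 0.877 with an estimated correlation). With the person as the replicate, 0 of 36 lists differed in response (exact 2-sided permutation test, smallest p = 0.0857, adjusted p = 0.918), where 4 people against 4 could reach p = 0.0286.

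Before exercise, obese and lean muscle were compared to ask which transcripts differed at rest. MYLK4, a myosin light chain kinase (chromosome 6, 2663629 to 2750966), was at 11.6 ± 7.30 CPM in lean and 69.1 ± 9.97 CPM in obese muscle, a difference of 2.71 ± 0.34 (limma, adjusted p = 0.0211). HOMER1, a scaffold protein of calcium signalling, was higher by 1.38 ± 0.21 (31 ± 8.12 and 80.0 ± 13.3 CPM). MYHAS, an antisense RNA in the fast myosin heavy chain cluster, was higher by 1.16 ± 0.16, but the strand setting of the counting was not given in the sources used here, so its reads and those of overlapping genes cannot be told apart. AKR1B15 was higher by 2.46 ± 0.36, with a near-identical paralog that can share its reads. CISH, a suppressor of cytokine signalling, was lower by -2.10 ± 0.32 (16.9 ± 7.0 and 3.26 ± 0.704 CPM, adjusted p = 0.0404). In all 7 genes were higher and 2 lower. The other lower gene was the antisense RNA ALDH1L1-AS2 at -2.0 ± 0.30, which lay under the 5 CPM of the naming rule and was named after its value was seen. Its reads likewise cannot be told apart from those of overlapping genes. Of all genes 1912 had an unadjusted p under 0.05, and the groups did not overlap for 7.26% of genes, where chance gives 2.86%. Genes just short of the test included KLF15, a glucocorticoid-induced transcription factor, at -1.43 ± 0.24 (adjusted p = 0.0518). The count was 2 without person 1, 5 without person 3, 4 or 6, 4 without person 5, 3 without person 8, 1 with no filter and 235 with DESeq2. The genes called changed as well. Of the 9 genes, 1 stayed called without person 1, 2 without person 4 or 8 and 7 without person 7. With no filter 0 of the 9 stayed called, and with DESeq2 all 9 did. The share of higher calls, 77.8%, was not stable, at 88.9% with quantile normalization, 57.0% with DESeq2, 54.3% with array weights and 40% without person 4.

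Of the 36 lists tested, 10 differed before exercise by camera, with 0 genes of any list past the test over all genes. Of 16 fast fibre genes 12 were higher in obese muscle, median 0.40, and 7 passed adjusted over the list alone (camera adjusted p = 0.00057, adjusted p = 0.708 with an estimated correlation). MYH1, the fast myosin heavy chain of IIx fibres, was at 4289 ± 3612 CPM in lean and 14782 ± 4313 CPM in obese muscle, a difference of 2.10 ± 0.50 that did not pass (adjusted p = 0.153). Of 14 slow fibre genes 13 were lower, median -0.52, and 0 passed on either scale (camera adjusted p = 0.00192, adjusted p = 0.708 with an estimated correlation). Of 56 cytosolic ribosomal protein genes 55 were lower, median -0.35 (camera adjusted p = 7.42e-13), of 56 oxidative phosphorylation genes 51, median -0.28 (camera adjusted p = 2.91e-06), of 24 fatty acid oxidation genes 22, median -0.32 (camera adjusted p = 0.00132), and of 19 endothelial markers 18, median -0.36 (camera adjusted p = 0.00132). Each of these 4 had adjusted p = 0.708 with an estimated correlation and 0 genes past the test on either scale. The other 4 lists called were lower in obese muscle, namely interferon-stimulated genes (median -0.30, camera adjusted p = 0.00966), immediate early genes (-0.36, 0.0131), metallothioneins (-0.97 over 3 genes, 0.0138) and glucocorticoid-responsive genes (-0.31, 0.0150). Each again had adjusted p = 0.708 with an estimated correlation. Adjusted over the list alone, 0 rose and 0, 1, 1 and 5 fell in these 4 lists, except for 1 glucocorticoid-responsive gene that was higher. The libraries also differed by GC content. Across the 98.8% of tested genes with a value, the obese minus lean difference before exercise had a Spearman's rho of -0.529 with the GC content of the transcript, with a median of 0.22 in the 20% of genes lowest in GC and -0.31 in the 20% highest. When this trend was removed from each library, a setting chosen after seeing the data, 20 genes were called before exercise in place of 9. Camera then called 3 lists as higher and 7 as lower in obese muscle, in place of 1 and 9.

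**Figure D3:**
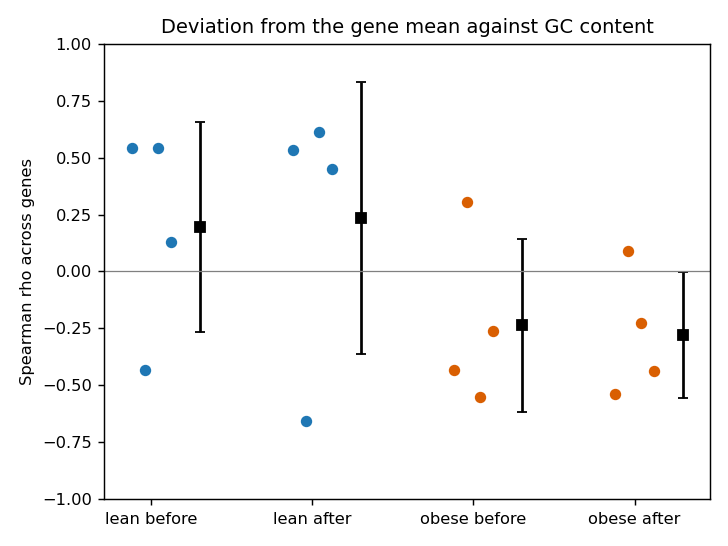
Spearman's rho, across genes, between a library's deviation from the gene mean (log2) and the GC content of the transcript, 1 point per library, with the group mean and SD (n = 4) as a black square and bar. The rho was below 0 in 1 of 4 lean libraries and in 3 of 4 obese libraries both before and after exercise.

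After exercise, 1 gene differed between obese and lean muscle. MYLK4 was at 12.6 ± 5.58 CPM in lean and 75.4 ± 16.1 CPM in obese muscle, a difference of 2.62 ± 0.30 (limma, adjusted p = 0.0282). The next genes did not pass, among them MYH1 at 2.08 ± 0.28 (adjusted p = 0.0725), CALML6 at 1.94 ± 0.31, the insulin receptor adaptor GRB10 at -1.27 ± 0.20, and LPL, lipoprotein lipase, at 199 ± 35.9 CPM in lean and 78.7 ± 24.1 CPM in obese muscle (-1.36 ± 0.22, adjusted p = 0.103). HK2 was at 146 ± 41.1 and 38.3 ± 21.9 CPM (-2.09 ± 0.41, adjusted p = 0.179). An unadjusted p under 0.05 was found for 1330 genes, and groups did not overlap for 4.21%, where chance gives 2.86%. All 16 fast fibre genes were higher in obese muscle, median 0.57, with 9 passing adjusted over the list alone (camera adjusted p = 7.16e-11, adjusted p = 0.558 with an estimated correlation), and all 14 slow fibre genes were lower, median -0.65, with 0 passing (camera adjusted p = 9.06e-06, adjusted p = 0.558 with an estimated correlation). Immediate early genes had a median of -0.66, with 27 of 30 lower (camera adjusted p = 2.88e-05, adjusted p = 0.558 with an estimated correlation), metabolic regulators -0.39 over 28 (camera adjusted p = 0.000569, adjusted p = 0.558 with an estimated correlation) and ribosomal protein genes -0.28 over 56 (camera adjusted p = 1.81e-09, adjusted p = 0.558 with an estimated correlation). Camera called 8 more of the 36 lists. Endothelial markers (median -0.42, camera adjusted p = 0.000397), macrophage markers (-0.50, 0.00196), angiogenesis targets (-0.38, 0.00421), fatty acid oxidation genes (-0.26, 0.00421), MHC class II genes (-0.48, 0.0238), cytokines and chemokines (-0.37, 0.0251) and interferon-stimulated genes (-0.23, 0.0386) were lower in obese muscle and red blood cell transcripts higher (1.05, 0.00861). With an estimated correlation their adjusted p ran from 0.558 to 0.680, and 0 of their genes passed over all genes or adjusted over the list alone. A GC trend was again present after exercise, with a rho of -0.516 across genes. Lean person 2, whose 2 libraries had a GC trend of opposite sign to those of the other lean people, decided the count. Without this person 1538 genes were called, and 39 were called when the GC trend was also removed. It was 0 without person 1, 4, 5, 6 or 8, 6 without person 7, 0 with edgeR, 141 with DESeq2 and 1363 with array weights.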

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

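The tests of depth, of spread and of the size of the change, of transcript length and body weight group, those on the interferon genes and those on the ribosomal protein and respiratory chain lists were chosen after the results were seen. The test of GC content within lists was fixed after the overall GC trend was seen and before its own result. An earlier pattern, lower ribosomal protein and respiratory chain transcripts in obese muscle before exercise, was set aside for the wider GC trend after that trend was seen. Its list medians were -0.35 and -0.28, then -0.32 and -0.29 with the GC trend removed and -0.31 and -0.22 with the length trend removed. Over people the mean difference was -0.37 for ribosomal proteins and -0.34 with the GC trend removed, so that trend did not account for most of it. The exact permutation p = 0.0286, the smallest possible, both times, but adjusted over 36 lists it was 0.468 without GC removal, so the difference itself was not established. The respiratory chain list had an exact permutation p = 0.143, and 0.171 with the GC trend removed, and stays undecided too.

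Fewer genes passed in obese than in lean muscle (17 and 613), although the difference in response was not past the test for any gene with limma (662 at an unadjusted p under 0.05, and 0 with edgeR and 2 with DESeq2). Depth is argued against as the cause, since the lean count was still 25.7 times the obese count (591 and 23) after all libraries were thinned to the same depth. Unequal SEs did not give these 2 counts, since the fit behind them shares 1 residual variance per gene. The SE of the obese change was 1 times that of the lean change (median over the 840 genes called on average). That ratio was fixed by construction, so it cannot test a wider spread among obese people, which stays open. The groups fitted alone, where spread can enter, gave 763 genes for lean and 0 for obese muscle. Over the 840 genes the median SD of the obese changes was 1.1 times the lean one. The mean change per person over these genes had an SD of 0.25 in obese and 0.10 in lean people. Smaller changes in obese muscle may account for the lower count and stay open too, with a mean change per person 0.627 times the lean one but an exact permutation p = 0.0857. The obese people were not alike. Their mean changes ran from 0.27 to 0.80, and the highest lay within the lean range of 0.70 to 0.91. The obese count was 87 without person 5, but 0 without person 7 and 1 without person 6.

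Obese and lean libraries differed by the GC content of transcripts, with rho = -0.529 across genes before exercise. GC-dependent recovery of reads in library preparation is a candidate explanation, as the trend lay within 29 of 30 lists of at least 10 genes (median rho -0.50) and not only between lists, but this support is weak since a GC shift tied to person or group would give the same. Transcript length is argued against, since removing the length trend kept 0.934 of the GC rho. Body weight group stays open and cannot be told apart from a preparation effect, with a rho per person of 0.21 ± 0.52 in lean and -0.26 ± 0.31 in obese people (SD, n = 4) and an exact permutation p = 0.2. The labels give no preparation batch, and the trend had the same sign in both libraries of 8 of 8 people.

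Interferon-stimulated genes were lower after exercise by -0.26 ± 0.12 (SD, n = 8 people). A scaling error that shifts all genes of a library is argued against. The median change of all genes was only -0.00616, and rescaling to equal medians kept 0.968 of the interferon change. Other forms of scaling were not tested for this list. Loss of endothelial cells from the later biopsies may contribute and stays open, since the endothelial list lay above the interferon list in 8 of 8 people but 7 of its members were higher and 12 lower (SD of the members 0.40), so that genes induced by exercise can hide a loss. Loss of immune cells stays open too, with the macrophage list above the interferon list in 6 of 8 people, although 11 of its members were higher and 5 lower and its mean rose by 0.14, since people varied with an SD of 0.49. No group was biopsied at both times without exercise, so an effect of exercise was not separated from time of day or a repeated biopsy.

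In 7 of 164 sets of 4 values the highest or lowest value stood far from the other 3, where chance gives about 8.2 (1 in 20). The 10 most abundant genes took 19.5% of reads in 1 lean library before exercise and 20.8% to 20.9% in the others (gap over range 0.883). The lymphocyte list changed by 0.52 in 1 lean person and by 0.03 to 0.06 in the others (0.938), the atrophy list by 0.04 against 0.39 to 0.43 (0.906) and the mitochondrially encoded mRNAs by -0.53 against -0.24 to -0.19 (0.839). MAFF changed by 6.83 in 1 lean person and by 4.46 to 4.53 in the others (0.973). In obese people the cytokine and chemokine list changed by -0.50 against -0.19 to -0.12 (0.840) and ANKRD9 by 0.99 against 0.57 to 0.60 (0.924).

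By camera, 10 lists differed in their response between obese and lean muscle, with 0 genes past the test over all genes. The lists with a positive obese minus lean difference were oxidative phosphorylation (median difference 0.17, adjusted p = 4.74e-08), red blood cell transcripts (1.41, 1.74e-05), fast fibre genes (0.34, 0.000131), ribosomal proteins (0.11, 0.000176) and mitochondrially encoded mRNAs (0.19, 0.0291). Those with a negative difference were heat shock genes (-0.16, 0.000996), collagens (-0.16, 0.0168), macrophage markers (-0.40, 0.0168), smooth muscle and pericyte markers (-0.25, 0.0184) and adipocyte markers (-0.38, 0.0291). All 10 were lost with an estimated correlation (adjusted p = 0.835 to 0.899).

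Other splits of the same people were refitted. For the 613 genes of lean and the 17 of obese muscle there are only 8 swaps of before and after, too few for a share under 0.05, and the highest other count was 0 for each. The splits compare how many genes were called, not which ones. Chance is argued against for the count of 840 genes in the mean (1 of 100 swaps, highest other 671). The same holds for the count of 9 genes in obese against lean muscle before exercise (1 of 35 splits, highest other 0). For the count of 9, 1 of 35 is the smallest share these splits can give, and no share was adjusted for the number of counts examined. Chance is not argued against for the count of 1 gene after exercise (6 of 35 splits, highest other 1594, a split that calls many genes and so points to a structure of the samples). That gene, MYLK4, was not itself tested by the splits, and it was also among the genes called before exercise. For the difference in response the splits decide nothing, since the real count was 0 and 35 of 35 splits reach it (highest other 2). Lists called by camera were as many in 60 of 100 swaps for the mean (10 real, highest other 20), 22 of 35 splits for the difference in response (10 and 19), 23 of 35 before exercise (10 and 19) and 18 of 35 after it (13 and 19), so chance is not excluded for these counts. In lean muscle 9 lists were called and the highest other was 13 (4 of 8 swaps), and in obese muscle 8 and 18 (6 of 8), again too few swaps for a share under 0.05.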

How the results depend on the processing

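Thinning to equal depth, the removal of GC and length trends and the exact test over people in place of camera were chosen after seeing the data; all other alternatives were planned. No named gene past the test changed sign under any alternative run. Of 159 calls on named genes, 96 were lost with no filter, 97 of 152 with no replicate block, 53 with no variance trend and 55 without person 2, against 0 with equal medians or thinning. Without the replicate block the counts were 72 for lean, 1 for obese, 149 for the mean and 1 for the genes shared by lean and obese. The block removes differences between people. In the same order lean, obese, mean and shared, no filter gave 99, 0, 298 and 0, where more genes were tested. For obese and shared, pseudocount 2 gave 4 and 4, a mean of at least 5 CPM 4 and 4, equal medians 36 and 34, robust variances 7 and 6, array weights 37 and 34, DESeq2 162 and 122, and the group fitted alone with its replicate block 0 and 0. No variance trend gave 375 for lean and 0 for obese and shared. For obese against lean before and after exercise, in that order, no filter gave 1 and 0, no variance trend 1 and 0, robust variances 16 and 2, array weights 35 and 1363, DESeq2 235 and 141, a random replicate block over all libraries 15 and 14, and GC removal 20 and 11. After exercise equal medians, quantile normalization and a mean of at least 5 CPM each gave 2, and edgeR 0. DESeq2 called 2 genes for the difference in response. With lean person 2 left out, GC removal gave 318 for lean and 39 after exercise, and length removal gave 222 for lean, 0 for obese, 0 shared, 16 before and 1479 after exercise. Leaving out 1 person gave 256 to 700 for lean, 0 to 87 for obese, 542 to 928 for the mean, 0 to 4 for the difference in response, 2 to 13 before, 0 to 1538 after (1538 without lean person 2) and 0 to 76 shared. For lists (9, 8, 10, 10, 10 and 13 by camera in lean, obese, mean, difference, before and after), an estimated correlation gave 0 in all 6, fry 4 in the mean and 0 elsewhere, and the exact test over people 0 in the 4 comparisons it covers. Where the exact test set 4 people against 4, it could pass after adjustment only with most lists at its smallest p. Camera with the GC trend removed gave 10, 8, 10, 11, 10 and 16 lists in the same order. Leaving out 1 person gave 9 to 14, 6 to 13, 5 to 12, 5 to 13, 8 to 13 and 11 to 20 lists. The collagen list reversed in the difference in response without person 5 (adjusted p = 0.769, and 1.60e-08 to 0.769 with 1 person left out). The cause was not tested except where named. Depth limits what can be read at low levels, but thinning changed no count of calls by over 1.5 times.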

Other observations

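The counts that follow are for exercise averaged over both groups, in which 840 of 14297 genes changed. Intramuscular lipid storage, synthesis and ceramide genes had 2 of 23 that rose (3 and 0 adjusted over the list alone), SREBF1 and PLIN2 among those that rose in lean muscle at 0.88 ± 0.20 and 0.38 ± 0.09. Insulin signalling genes had 2 of 21 that rose and 1 that fell (6 and 1 adjusted over the list alone; camera adjusted p = 0.0266, adjusted p = 0.554 with an estimated correlation), and glycolysis genes 2 of 26 that rose and 3 that fell (2 and 3). Unfolded protein response genes had 1 of 18 that rose and 2 that fell (2 and 3), with DDIT3 at 1.2 ± 0.22 and SESN2 at -0.80 ± 0.21 in lean muscle. Camera also called heat shock genes (4 of 24 rose and 1 fell, camera adjusted p = 0.00496) and atrophy genes (5 of 19 rose and 0 fell, 0.0299) as higher, and mitochondrially encoded mRNAs (0 of 13 rose or fell, 0.00612), oxidative phosphorylation genes (0 of 56, 0.0320) and fatty acid oxidation genes (0 of 24, 0.0320) as lower. With an estimated correlation the adjusted p was 0.720 for atrophy genes and 0.877 for the other 4. Adjusted over the list alone, 6, 6, 0, 0 and 0 rose and 2, 1, 0, 0 and 3 fell in these 5 lists. Of 24 tricarboxylic acid cycle genes 2 rose and 0 fell (2 and 0), of 20 antioxidant genes 0 and 1 (0 and 4), of 15 NF-kB targets 1 and 0 (1 and 1), of 14 slow fibre genes 1 and 0 (1 and 0), and of 28 collagen and matrix genes 1 and 0 (1 and 0).

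Markers of resident and blood-borne cells had few genes past the test for exercise on average. Of 7 Schwann cell and nerve markers 3 rose and 0 fell (3 and 0 adjusted over the list alone). Their median was only 0.012, with 4 higher and 3 lower. Of 19 endothelial markers 2 rose and 1 fell (3 and 2). The listed macrophage and lymphocyte markers averaged only 1.66 and 0.508 CPM, so a lack of calls does not show that they were unmoved. Of 10 satellite cell markers, 17 fibroblast and progenitor markers, 9 MHC class II genes, 16 macrophage markers and 5 lymphocyte markers, 0 rose and 0 fell with limma over all genes or adjusted over the list alone, with camera adjusted p of 0.229, 0.944, 0.498, 0.353 and 0.595. The 24 ribosome biogenesis genes (camera adjusted p = 0.501) and 56 ribosomal protein genes (0.916) also had 0. Of 9 cytokine genes 0 rose and 0 fell (0 and 2 adjusted over the list alone) and of 3 metallothioneins 1 fell. The skin, mast cell, platelet and neutrophil lists had 2, 2, 2 and 1 tested genes and were not tested as lists. HBB, the most abundant of the red blood cell transcripts, was higher after exercise in 4 of 4 obese people and in 1 of 4 lean people.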
